A study of Mus musculus with 11 samples.

How the data were processed

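Liver RNA of 11 samples was measured by RNA sequencing. Per the labels' protocols, RNA was extracted from frozen liver, libraries were made with a stranded mRNA kit, and paired-end reads of 48 bases were read on an Illumina HiSeq instrument. RNA integrity numbers between 8.4 and 9.2 are given for 7 of the samples and none is given for 4. Per the submitters' processing notes, bcl2fastq 1.8.4, FastQC 0.11.3, Bowtie, SAMtools 0.1.19, bedtools 2.17.0, R 3.1.2 and edgeR 3.8.6 were used, with the mouse build mm10. The notes used here give no order, settings or gene annotation.

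The deposited table gives 1 value per gene and library for 13636 genes. The values are a scaled signal: the deposited columns sum to between 605536 and 1504311, while columns of plain CPM share 1 upper limit. Within each library all values (100%) were whole multiples of a single step, to a tolerance of 1e-06, so that reads per gene could be recovered. The step was the smallest value above 0 or, where that value stood for 2 reads, a division of it. The effective library sizes divided by the column totals gave factors from 0.665 to 1.65 whose product was 1, and with TMM factors recomputed from the recovered reads the log2 changes had a median shift of 0 and 4363 of 4363 and 5059 of 5059 calls were kept. These values are therefore called scaled CPM. All rows had at least 1 CPM in 3 libraries when computed from column totals, and 268 rows did not on the scaled values. Some rows share reads: 54 rows were identical to another row, in 24 distinct profiles, among them Mup copies, so that reads of near-identical genes were counted more than once, and totals are totals of such counts. Values of Mup genes, of Saa1 and Saa2, of Oas1a and Oas1g, of Aldh18a1 and Entpd1, and of Cyp3a genes are uncertain where the authors' counting could split or repeat reads.

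Differences were tested with limma 3.58.1 (R 4.3.3) on log2(value + 1), with 1 fit of 3 group means over all 11 libraries, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment over all 13636 genes, at a threshold of 0.05. The design had assumed CPM, and the scaled signal was treated in the same way. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 23 lists that had at least 5 measured members. Lymphocytes (4 measured) and pancreas, fat and muscle (3 measured) were not tested, and 0 mitochondrially encoded genes were in the table. All gene lists, that of miR-30 targets included, were written from memory and not checked against a database. One member of the interferon list was matched through an older symbol. The expression of single genes, of lists and of the site score was tested on simulated data first. In data of 13636 genes with 100 genes changed by 2-fold and 100 by 4-fold, the fit recovered 83% and 97% for mimic against scramble, 87% and 96% for mimic against PBS and 84% and 93% for scramble against PBS, with 5, 11 and 8 false calls. A simulated 2-fold shift of the acute phase list in mimic against scramble was called, with 0 other lists. A simulated site effect of -0.2 on 11846 genes came back as -0.20 in mimic against scramble.

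Gene positions and 3′ UTRs came from GENCODE M21 on GRCm38, the same assembly as mm10. Of the rows, 12060 matched by symbol, 412 by an older symbol and 1164 did not match. For 11846 rows the longest annotated 3′ UTR was searched for the 7-base match to the miR-30 seed and for the 8-base site with a further A. The score of a library was the mean over genes with a site minus the mean over genes without one, of values centred per gene on the mean of the group means. Scores and Mttp were compared with two-sided exact permutation tests over libraries, adjusted over 3 comparisons. Length was matched in 20 bins.

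Groups came from the sample titles. Before the data were examined, the comparisons, lists, alternatives and the rule for named genes were fixed. The rule took, per comparison and direction, the 8 called genes with the smallest p and the 4 with the biggest change among called genes whose groups do not overlap, or the 3 with the smallest p where none was called, leaving out predicted genes, and in addition Mttp and up to 4 members of each list with the smallest p. Alternatives covered the pseudocount (0.25), filters on low values, the scaling, the replicate number as a block, the libraries in the fit, the variance model, library weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library. On the recovered reads the edgeR quasi-likelihood test called 4422 genes in mimic against scramble, 5053 in mimic against PBS and 0 in scramble against PBS. Scaling by median-of-ratios factors, division by library totals, and the fits without mimic replicates 1 and 4, also without PBS replicate 2, were chosen after seeing the data. Counts between libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom from 61.0 to 1333, so that each library was counted as 1 sample. Python 3.11.15 with numpy and matplotlib made the scores and figures.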

Results

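Liver RNA was sequenced from male C57BL/6J mice, a common inbred laboratory strain. The mice went on a Western diet at 8 weeks of age and later received PBS, a scramble oligomer or a mimic of the microRNA miR-30c over 6 weeks, with the dose of an oligomer raised from 2.5 to 7.5 mg/kg by way of 5.0 mg/kg. There were 4 PBS libraries, 3 scramble libraries and 4 mimic libraries. The table held 13636 genes. The reads counted over all genes ranged from 39705157 to 101380174 per library. The means were 74205926 ± 18202525 in the PBS group (SD, n = 4), 79752373 ± 7924750 in the scramble group (SD, n = 3) and 52702550 ± 9167564 in the mimic group (SD, n = 4). The labels number the libraries within each group but do not say that each came from a separate mouse, so p-values measure the spread between these libraries. Values are scaled CPM (read counts relative to library size) as deposited, and log2 changes are on the log2(value + 1) scale, which understates the change of genes with low values.

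Comparing the mimic with the scramble oligomer asks what the miR-30c sequence adds to the injection of an oligomer. The serum amyloid A genes, which encode acute phase proteins secreted by the liver, rose most among the genes named here, together with Lcn2. Saa1 (chromosome 7, 46740497 to 46742980, GRCm38) averaged 18.6 ± 0.885 in the scramble group (SD, n = 3) and 5088 ± 2124 in the mimic group (SD, n = 4), a log2 change of 7.92 ± 0.46 (SE). Saa2 changed by 9.22 and Saa3 by 8.12. Lcn2, which encodes the iron-scavenging protein lipocalin 2 (chromosome 2, 32384633 to 32388252), went from 2.01 ± 0.550 to 1314 ± 761 (SD, n = 3 and 4). Gpnmb, a gene of lipid-laden macrophages (chromosome 6, 49036546 to 49070929), went from 0.114 ± 0.0316 to 39.8 ± 8.54, a log2 change of 5.17 ± 0.20 (SE). Slfn4, Chil3 and Cd93, all known from myeloid cells, had log2 changes of 2.73, 2.87 and 2.45. Acot1, a cytosolic acyl-CoA thioesterase (chromosome 12, 84009490 to 84018371), fell from 54.8 ± 5.24 to 5.00 ± 2.69, a log2 change of -3.32 ± 0.29 (SE). The drug-metabolizing cytochrome P450 gene Cyp3a11 and the organic anion transporter Slco1a1 both changed by -2.45, and the keratin gene Krt23 by -2.42. Slc25a32, the mitochondrial folate carrier, changed by -0.91, Aldh18a1, an enzyme of proline synthesis, by -1.01, Entpd1, an ectonucleotidase, by -0.97, Hhip, an inhibitor of hedgehog signalling, by -0.99, and Etl4 by -0.87. Adjusted p of these 17 genes was at most 7.7e-05 with limma. Aldh18a1 and Entpd1 lie close together on chromosome 19, and their values ran in parallel in each library. They were 200 and 207 in PBS replicate 1 and 97.4 and 104 in mimic replicate 1. Their changes may rest on shared reads and are not counted as independent.

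**Figure D1:**
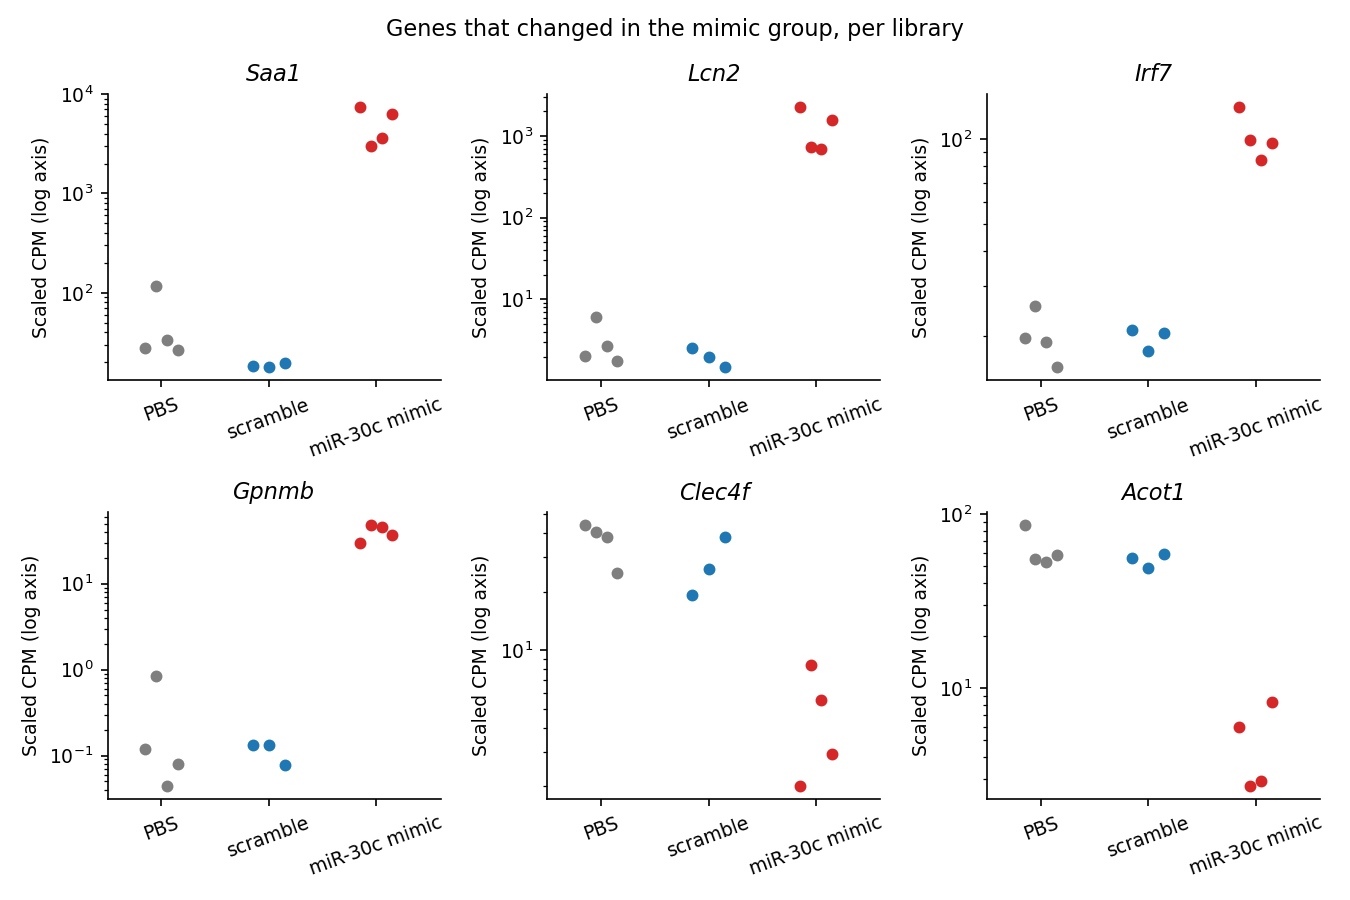
Scaled CPM on a log axis for 6 genes, with 1 point per library of the PBS group (4), the scramble group (3) and the mimic group (4). All 4 mimic libraries lie above all 7 others for Saa1, Lcn2, Irf7 and Gpnmb and below them for Clec4f and Acot1.

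Of 4 measured lymphocyte genes 2 were higher, and of 3 genes of pancreas, fat and muscle 1, Cfd, was lower. In all, 4363 of the 13636 genes passed an adjusted p of 0.05 with limma, 2363 higher and 2000 lower in the mimic group. Of these, 416 were higher and 137 lower by at least 2-fold, and 52 and 16 by at least 4-fold, counted on the log2(value + 1) scale. Genes with low values can change by more and not be counted. Hhip, for example, went from 1.21 in the scramble group to 0.107 in the mimic group at a log2 change of -0.99. For 4090 of the 4363 the values of the groups did not overlap, and over all genes this was so for 40.8%, where chance gives 5.71%. The count was 2824 without scramble replicate 1, 2816 among genes with a mean of at least 5, and 2548 without mimic replicates 1 and 4. When reads were divided by the library totals alone, without the authors' scaling factors, the median gene moved up by 0.52 on the log2 scale. The split was then 5498 higher and 110 lower, so that the directions given here are relative to the bulk of genes. The totals include the rows of the major urinary protein (Mup) genes. These held on average 50.9% of the counted reads in the scramble group and 29.0% in the mimic group. A fall in this share alone raises all other genes when totals are the divisor. How much of the shift it accounts for was not tested. Changes with library totals in this comparison stand against a median of all genes of 0.49.

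Of 35 acute phase genes, 22 were higher and 1 was lower over all genes tested, and 23 and 1 adjusted over the list alone, with a median log2 change of 1.63. The one that was lower, named after its values were seen, was the transcription factor gene Cebpb, at -0.31, or 0.27 with library totals. It averaged 78.7 in the PBS group, 100 in the scramble group and 80.5 in the mimic group, and was not called against PBS, at 0.03. The list was called by camera at an adjusted p of 2.5e-11, and had an adjusted p = 0.29 with an estimated correlation. Of 51 interferon response genes, 36 were higher and 0 lower, and 41 and 0 adjusted over the list alone, with a median of 1.06 and a camera adjusted p of 4.1e-15, against an adjusted p = 0.29 with an estimated correlation. Irf7, the transcription factor of the interferon response, rose from 19.7 ± 1.79 to 103 ± 19.7 (SD, n = 3 and 4), and the antiviral oligoadenylate synthetases Oas1a, Oas1g and Oas3 rose by 2.59, 2.30 and 1.60 on the log2 scale. The share of counted reads in the Saa rows was 2.61% and 2.05% in mimic replicates 1 and 4, 0.699% and 0.720% in replicates 2 and 3, and between 0.0101% and 0.0211% in the 7 control libraries. These shares also depend on the library totals. In scaled CPM Saa1 was 7489 and 6231 in mimic replicates 1 and 4 and 3008 and 3626 in replicates 2 and 3, a smaller contrast.

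Markers of macrophages moved in both directions. Of 29 genes in the list of Kupffer cells and macrophages, 17 were higher and 5 lower, and 18 and 5 adjusted over the list alone, with a median of 1.10, a camera adjusted p of 2.3e-05 and an adjusted p = 0.31 with an estimated correlation. Besides Gpnmb, the genes that rose included Lgals3, which encodes galectin 3, from 2.11 ± 0.183 to 27.1 ± 4.42, and the lipid receptor gene Trem2, from 0.169 ± 0.0196 to 4.70 ± 1.57 (SD, n = 3 and 4). Itgam, an integrin of myeloid cells, rose by 1.86 on the log2 scale. The 5 that fell, named after their values were seen, were Clec4f, Timd4, Vsig4, Cd163 and Folr2, markers of the macrophages resident in the liver. Their log2 changes were -2.42, -1.69, -1.69, -1.74 and -0.79, and Timd4 went from 2.84 ± 1.26 to 0.155 ± 0.175 (SD, n = 3 and 4). Of 9 genes of neutrophils and erythrocytes, 5 were higher and 0 lower, with the same counts adjusted over the list alone. These were neutrophil genes, among them S100a8 and S100a9, which encode the subunits of calprotectin and changed by 2.61 and 2.85, and Csf3r and Ltf, which changed by 1.51 and 1.41. Their list had a camera adjusted p of 0.0027 and an adjusted p = 0.28 with an estimated correlation.

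Of 31 genes of stellate cells and fibrosis, 21 were higher and 1 lower, and 22 and 2 adjusted over the list alone, with a median of 1.02, a camera adjusted p of 1.6e-09 and an adjusted p = 0.29 with an estimated correlation. Col3a1 rose from 7.30 ± 1.79 to 85.4 ± 28.6 and Col1a2 from 3.74 ± 0.321 to 39.6 ± 15.5 (SD, n = 3 and 4), the basement membrane collagen Col4a2 rose by 1.62, and the matrix protein gene Sparc rose by 2.04. The one called lower over all genes, also named after its values were seen, was Reln, which encodes the matrix protein reelin, at -0.94. Genes of the sinusoidal endothelium were not called as a list. Of 25, 3 were higher and 4 lower, with the same counts adjusted over the list alone, a median of -0.23 that was 0.31 with library totals, a camera adjusted p of 0.11 and an adjusted p = 0.67 with an estimated correlation. Ehd3 and Ptprb of that list changed by -1.06 and -0.77. Of 8 bile duct genes, 5 were higher and 1, Krt23, was lower, and 7 and 1 adjusted over the list alone. Spp1, which encodes osteopontin, rose by 1.02 and the cytoskeletal linker gene Ezr by 0.66. Their list had a camera adjusted p of 0.031 and an adjusted p = 0.31 with an estimated correlation.

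Of 44 genes of fatty acid oxidation and targets of the nuclear receptor PPARA, 0 were higher and 30 lower, and 33 were lower adjusted over the list alone. The median was -0.56, or 0.03 with library totals, where 11 were still called lower and 1 higher. The camera adjusted p was 1.4e-13, with an adjusted p = 0.20 with an estimated correlation. Besides Acot1, the peroxisomal thiolase Acaa1b fell from 941 ± 20.4 to 433 ± 49.0 and the isomerase Eci1 from 71.1 ± 2.63 to 39.9 ± 2.31 (SD, n = 3 and 4), and the fatty aldehyde dehydrogenase Aldh3a2 changed by -1.33. Of 74 nuclear genes of the respiratory chain, 0 were higher and 19 lower, and 18 were lower adjusted over the list alone, with a median of -0.16 that was 0.41 with library totals. With quantile normalization 1 was higher and 4 were lower. Sdha and Uqcrc2, subunits of complexes of the chain, changed by -0.62 and -0.43, and Uqcrc2 was at 0.15 with library totals. Their list had a camera adjusted p of 7.4e-05 and an adjusted p = 0.47 with an estimated correlation. Of 30 genes of fatty acid and triglyceride synthesis, 2 were higher and 10 lower, with the same counts adjusted over the list alone, and a median of -0.24 that was 0.34 with library totals. The elongase Elovl6 fell by 1.17, while the acyltransferase Mogat2 rose by 0.70 at values below 1. Their list had a camera adjusted p of 0.012 and an adjusted p = 0.30 with an estimated correlation.

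Of 35 male-biased genes under growth hormone control, 0 were higher and 17 lower, and 20 were lower adjusted over the list alone, with a median of -1.05 that was -0.46 with library totals. The steroid dehydrogenase Hsd3b5 fell from 108 ± 14.5 to 24.6 ± 7.52 (SD, n = 3 and 4), the fatty acid hydroxylase Cyp4a12a changed by -1.16 and Keg1, an acyltransferase-like gene, by -1.15. The list had a camera adjusted p of 1.3e-08 and an adjusted p = 0.29 with an estimated correlation. It includes the major urinary protein (Mup) genes, near-identical copies whose reads cannot be told apart with certainty. The 20 Mup rows held between 44.4% and 61.9% of the counted reads in the 7 control libraries, 14.5% and 13.5% in mimic replicates 1 and 4, and 40.4% and 47.8% in mimic replicates 2 and 3. Reads of near-identical copies were counted more than once, so these are not shares of distinct reads. Of 14 female-biased genes, 1 was higher and 5 were lower, and 1 and 6 adjusted over the list alone, with a median of -0.42 that was 0.06 with library totals. Cyp3a41b, Cyp3a44 and the thioesterase Acot3 changed by -1.92, -1.74 and -2.13, and the steroid hydroxylase Cyp17a1 by 1.39. Their list had a camera adjusted p of 0.023 and an adjusted p = 0.29 with an estimated correlation.

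**Figure D2:**
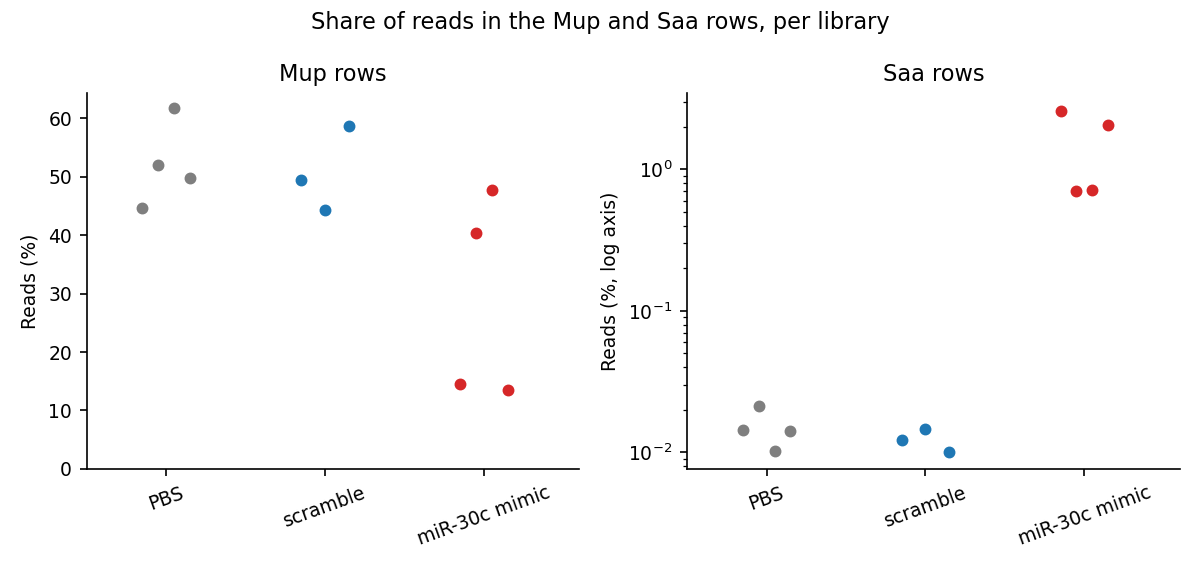
Percent of counted reads in the Mup rows (left, linear axis) and in the Saa rows (right, log axis), with 1 point per library of the PBS group (4), the scramble group (3) and the mimic group (4). Reads of near-identical copies were counted more than once, so these are not shares of distinct reads. The Mup share was 13.5% to 47.8% in the mimic group, and the Saa share was at least 0.699% there and at most 0.0211% elsewhere.

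Of 49 genes of xenobiotic metabolism, 6 were higher and 19 lower, and 6 and 21 adjusted over the list alone, with a median of -0.50 that was 0.04 with library totals. The carboxylesterases Ces2a and Ces2c changed by -0.87 and -2.21, and the list had a camera adjusted p of 0.00027 and an adjusted p = 0.31 with an estimated correlation. Of 28 genes of bile acid synthesis and transport, 1 was higher and 5 were lower, with the same counts adjusted over the list alone and a median of -0.17 that was 0.38 with library totals. Slco1b2, a bile acid and drug transporter, changed by -0.76, and the list had a camera adjusted p of 0.013 and an adjusted p = 0.29 with an estimated correlation. Of 23 circadian clock genes, 0 were higher and 10 lower, and 11 were lower adjusted over the list alone, with a median of -0.43 that was 0.15 with library totals. The clock repressors Cry1 and Nr1d2 changed by -0.88 and -0.43, with Nr1d2 at 0.15 with library totals, and the list had a camera adjusted p of 0.0022 and an adjusted p = 0.30 with an estimated correlation. Of 27 genes of glucose metabolism and insulin signalling, 2 were higher and 8 lower, and 2 and 11 adjusted over the list alone, with a median of -0.32 that was 0.21 with library totals. Irs2, an insulin receptor substrate, the transcription factor gene Foxo3 and the liver glycogen synthase Gys2 changed by -1.08, -0.89 and -0.87, and the list had a camera adjusted p of 0.0032 and an adjusted p = 0.20 with an estimated correlation. Of 26 genes of cholesterol biosynthesis, 10 were higher and 2 lower, with the same counts adjusted over the list alone and a median of 0.25. Dhcr7, the last enzyme of the pathway, rose from 4.86 ± 0.323 to 14.2 ± 1.21 (SD, n = 3 and 4), Mvk rose by 0.87 and the regulator Srebf2 by 0.54, and the list had a camera adjusted p of 0.0065 and an adjusted p = 0.31 with an estimated correlation.

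Of 80 cytosolic ribosomal protein genes, 26 were higher and 0 lower, and 30 were higher adjusted over the list alone, with a median of 0.23. Rps10 and Rplp0 rose by 0.48 and 0.45, and the list had a camera adjusted p of 1.4e-07 and an adjusted p = 0.33 with an estimated correlation. Of 25 genes of the cell cycle and targets of p53, 12 were higher and 1 lower, and 14 and 1 adjusted over the list alone, with a median of 0.34. The DNA helicase subunits Mcm5 and Mcm6 rose by 0.84 and 1.01, while the stress gene Gadd45a was the one that fell, by 1.22 against scramble but by 0.45 against PBS, with averages of 6.51 in the PBS group, 11.7 in the scramble group and 4.40 in the mimic group. The list had a camera adjusted p of 0.0018 and an adjusted p = 0.29 with an estimated correlation. Of 31 genes of endoplasmic reticulum stress, 3 were higher and 3 lower, and 2 and 3 adjusted over the list alone. Their median of 0.04 and mean of 0.08 were positive while camera gave the list a downward direction, at an adjusted p of 0.77, with an adjusted p = 0.92 with an estimated correlation. Aldh18a1 was among those that fell and the stress gene Nupr1 among those that rose, by 0.82 at values below 2.

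**Figure D3:**
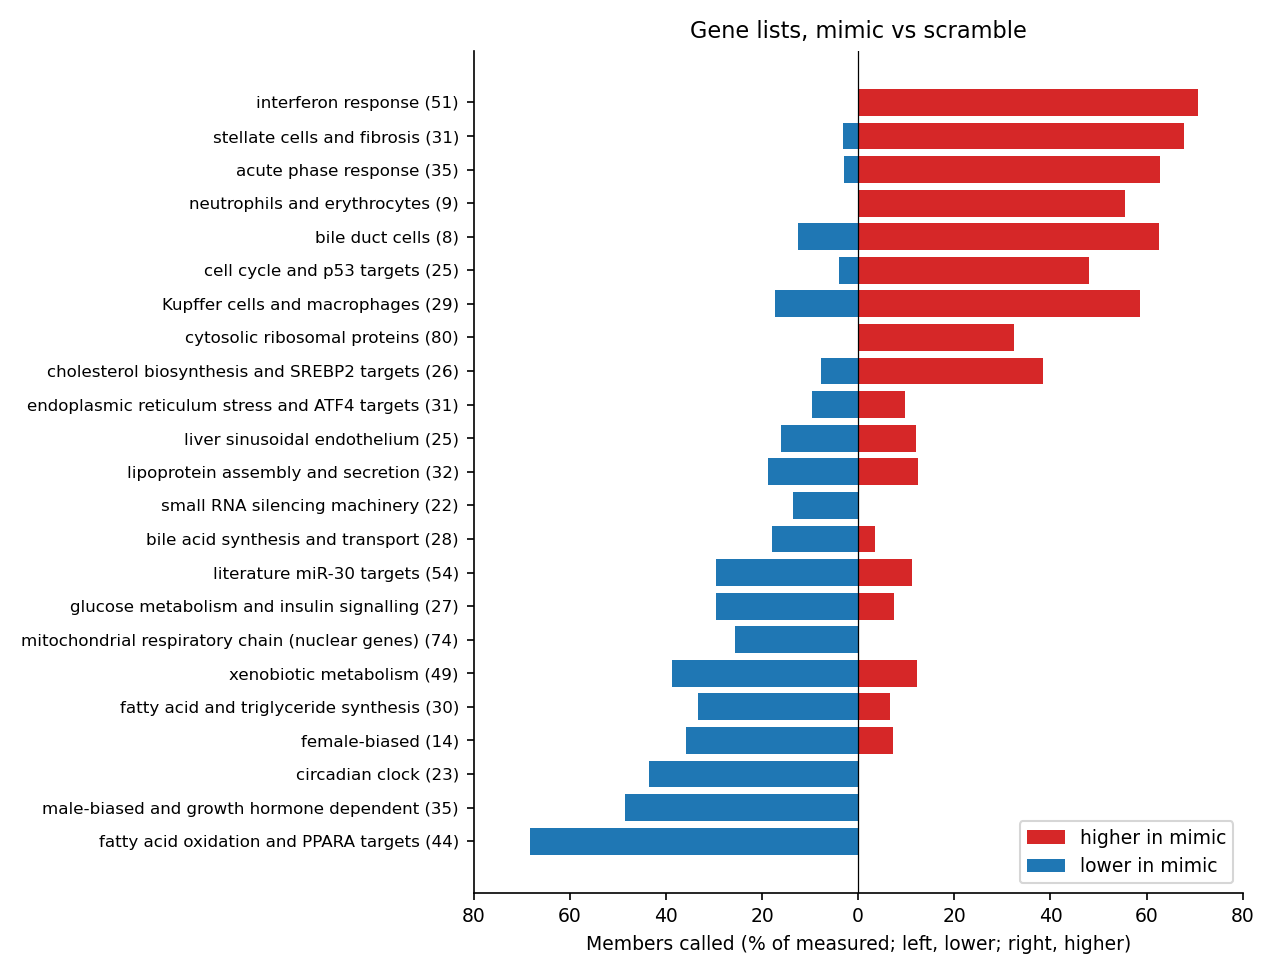
Percent of the measured members of each of 23 gene lists that were called higher (red, to the right) or lower (blue, to the left) in the mimic group than in the scramble group, with the number of measured members in parentheses. Interferon response had 36 of 51 higher and 0 lower, and fatty acid oxidation had 30 of 44 lower and 0 higher. With library totals the medians of the lists below 0, except the male-biased list at -0.46, lay above 0. All of these lists stayed below the median of all genes, which was 0.49 with library totals.

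Mttp encodes the microsomal triglyceride transfer protein, which loads lipid onto apolipoprotein B, and is a known target of miR-30c. Mttp lies on chromosome 3 at 138089854 to 138144968 on the minus strand (GRCm38). Its value was 69.3 ± 8.83 in the mimic group (SD, n = 4), 122 ± 7.12 in the scramble group (SD, n = 3) and 133 ± 7.02 in the PBS group (SD, n = 4). Its log2 change was -0.82 ± 0.10 (SE) against scramble and -0.94 ± 0.09 against PBS, with adjusted p of 0.00019 and 4.4e-05 by limma. It was lower in all 4 mimic libraries than in all 7 others, and the two-sided exact permutation test gave p = 0.0286 for each, the smallest it can give, and 0.0429 after adjustment over the 3 comparisons. Scramble and PBS differed in Mttp by -0.12 ± 0.10 (SE), exact permutation p = 0.171. With library totals the changes were -0.23 and -0.33 with adjusted p of 0.45 and 0.23 by limma, where the medians of all genes were 0.49 and 0.51. The annotated 3′ UTR of Mttp, in its last exon at 138089854 to 138091057, holds 1 full match to the miR-30 site, TGTTTACA, at 138090977 to 138090984. The surrounding sequence on the transcript strand is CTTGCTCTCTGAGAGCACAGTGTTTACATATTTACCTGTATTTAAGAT.

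Of 32 genes of lipoprotein assembly and secretion, 4 were higher and 6 lower in mimic against scramble, with the same counts adjusted over the list alone. The median was 0.01, while the mean was -0.06 and camera gave a downward direction at an adjusted p of 0.53, with an adjusted p = 0.52 with an estimated correlation. Mia3 and Sar1b, which act in the export of large cargo from the endoplasmic reticulum, changed by -0.78 and -0.49, with Sar1b at 0.09 with library totals, and Tm6sf2, a lipoprotein lipidation factor, by 1.09. Mia3 lies on chromosome 1 at 183326725 to 183369553 and also has 1 full site in its 3′ UTR. Of 54 genes remembered from the literature as miR-30 targets, Mttp among them, 6 were higher and 16 lower, and 6 and 20 adjusted over the list alone, with a median of -0.16 that was 0.36 with library totals. Ppp3ca, a calcineurin subunit, the stress kinase gene Map3k5 and the autophagy gene Becn1 changed by -0.70, -0.90 and -0.33, with Becn1 at 0.23 with library totals. The 3′ UTR searched for Ppp3ca held 0 miR-30 sites of 7 bases, while those of Map3k5 and Becn1 held 1 each. The list had a camera adjusted p of 0.0062 and an adjusted p = 0.29 with an estimated correlation. Of 22 genes of the small RNA silencing machinery, 0 were higher and 3 lower, with the same counts adjusted over the list alone and a median of -0.15 that was 0.38 with library totals. The 3 were Ago2, a core protein of the silencing complex, Tnrc6b, its partner, and the deadenylase gene Cnot6l, with changes of -0.69, -0.55 and -0.39, of which Tnrc6b and Cnot6l were at 0.0055 and 0.17 with library totals, and the list had a camera adjusted p of 0.022 and an adjusted p = 0.31 with an estimated correlation. Several list calls of mimic against scramble were lost in other settings. With quantile normalization these were the lists of bile acids, fatty acid and triglyceride synthesis, female-biased genes, glucose metabolism, the respiratory chain and silencing. Among genes with a mean of at least 5 they were the lists of bile acids, the cell cycle, fatty acid and triglyceride synthesis, glucose metabolism and silencing, and the bile duct list and that of neutrophils and erythrocytes had too few members to be tested. With library totals the bile duct, respiratory chain and silencing calls were lost, without mimic replicates 1 and 4 together the bile duct, circadian and silencing calls, and without mimic replicate 2 the female-biased call. Other calls were gained, all downward: the sinusoidal endothelium with library totals, without mimic replicate 2 and without scramble replicate 1, and endoplasmic reticulum stress without mimic replicates 1 and 4 together.

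Whether genes with sites for the mimic were lower as a class was asked with a score per library, the mean of the 1891 genes with a 7-base miR-30 site in the 3′ UTR minus the mean of the 9955 genes without one. The score was -0.100 ± 0.0231 in the mimic group (SD, n = 4), 0.0503 ± 0.0269 in the scramble group (SD, n = 3) and 0.0496 ± 0.0547 in the PBS group (SD, n = 4). The difference was -0.15 against scramble and -0.15 against PBS, each with a two-sided exact permutation p = 0.0286, the smallest it can give, and 0.0429 adjusted over the 3 comparisons. Scramble and PBS differed by less than the spread between libraries, at an exact permutation p of 1. Of the genes with a site, 23.5% were called lower and 10.9% higher in mimic against scramble, compared with 13.2% and 19.3% of those without. The median log2 change was 0.03 for genes without a site, -0.09 for 925 genes with a 7-base site only, -0.14 for 966 genes with the full 8-base site and -0.18 for 340 genes with 2 or more sites. The median 3′ UTR length of these classes was 983, 2303, 2496 and 3694 bases in the same order, so that their medians do not separate sites from length. Genes with a site have long 3′ UTRs, with a median of 2380 bases against 983, and against genes of matched length the difference was -0.09. Among 200 reordered 7-base sequences the median difference was -0.11, and 3 were as low as the miR-30 site.

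**Figure D4:**
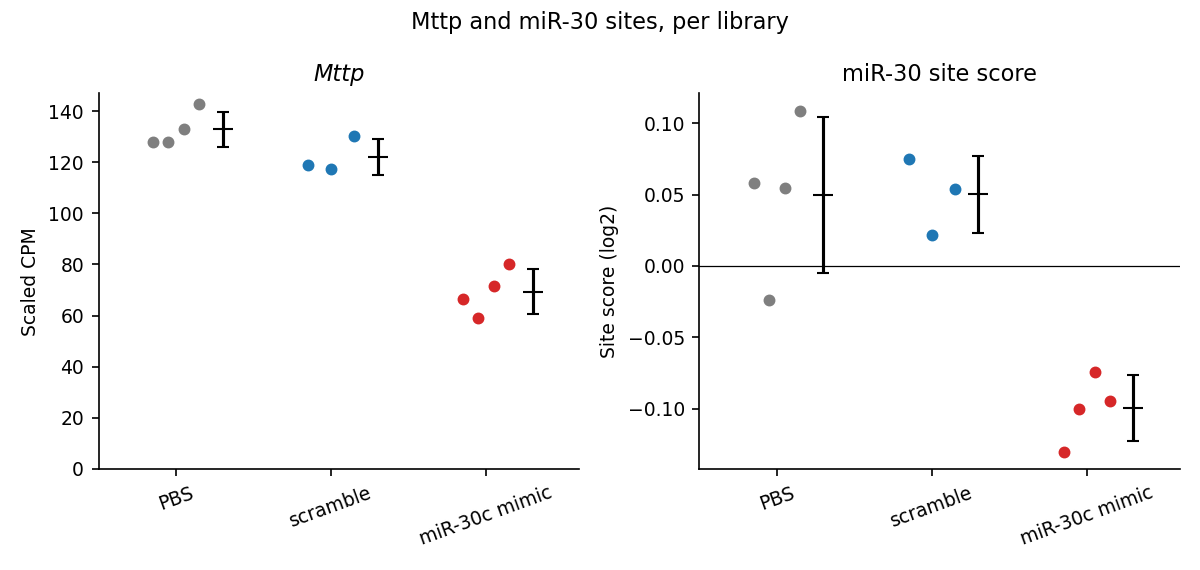
Mttp in scaled CPM (left) and the miR-30 site score in log2 units (right), with 1 point per library of the PBS group (4), the scramble group (3) and the mimic group (4), and the mean with its SD beside each group. Mttp averaged 69.3 in the mimic group against 122 and 133, and the score averaged -0.100 against 0.0503 and 0.0496.

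Comparing the mimic with PBS asks for the effect of the mimic and its injection together. Lcn2 went from 3.14 ± 1.98 in the PBS group to 1314 ± 761 in the mimic group (SD, n = 4 and 4), and Saa1 from 51.0 ± 43.7 to 5088 ± 2124, where PBS replicate 2 stood at 116 and the other PBS libraries at 26.3 to 33.7. Slfn4, Gpnmb, Cd93, Chil3, Saa2 and Saa3 rose by 2.68, 5.02, 2.32, 2.77, 8.33 and 7.46, and Mmp12, the macrophage elastase, by 3.15, or 3.22 against scramble. Acot1, Slco1a1, Krt23 and Hhip changed by -3.50, -2.29, -2.71 and -0.97, Aldh3a2 by -1.45, and Cyp3a41b by -2.09. The monoglyceride lipase Mgll changed by -1.16, Dennd4a by -0.68 and Clec4f by -2.83. Cfd, which encodes the fat cell protein adipsin, was 23.3 ± 14.4 in the PBS group, 56.6 ± 56.9 in the scramble group and 1.20 ± 1.95 in the mimic group (SD, n = 4, 3 and 4), a change of -3.56 against PBS with an adjusted p of 0.024 by limma.

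In mimic against PBS 5059 genes passed the threshold with limma, 2733 higher and 2326 lower. Of these, 376 were higher and 136 lower by at least 2-fold on the log2(value + 1) scale. The count of genes that passed was 3273 among genes with a mean of at least 5 and 2894 without mimic replicates 1 and 4, or 4276 when PBS replicate 2 was left out too. With library totals the split was 6882 higher and 120 lower. Of 35 acute phase genes 24 were higher and 0 lower, of 51 interferon genes 35 and 0, of 29 macrophage genes 15 and 5, of 31 stellate cell genes 23 and 1, of 44 fatty acid oxidation genes 0 and 34, and of 35 male-biased genes 0 and 19. Adjusted over the list alone these were 25 and 0, 37 and 0, 17 and 5, 23 and 1, 0 and 37, and 0 and 24. Camera called 17 of 23 lists, 9 upward and 8 downward, and 0 with an estimated correlation, where adjusted p ran from 0.28 to 0.82. The calls of glucose metabolism, the respiratory chain, silencing and xenobiotic metabolism were lost with quantile normalization, and that of silencing also without any 1 of 4 libraries, with a pseudocount of 0.25 and with a replicate block. Without mimic replicates 1 and 4 together the circadian and silencing calls were lost. Among genes with a mean of at least 5 the calls of the cell cycle, the circadian clock, glucose metabolism, silencing and xenobiotic metabolism were lost, the bile duct list and that of neutrophils and erythrocytes were not tested, and with library totals those of the bile duct, the respiratory chain and silencing. Downward calls were gained for the sinusoidal endothelium with library totals and without PBS replicate 2, PBS replicate 3 or mimic replicate 2, and for bile acids with library totals and without PBS replicate 2. They were also gained for fatty acid and triglyceride synthesis with library totals, for the female-biased genes with library totals, without mimic replicate 4 and without mimic replicates 1 and 4 together, and for endoplasmic reticulum stress without those 2. Bile acid synthesis, fatty acid and triglyceride synthesis and the female-biased genes were called against scramble but not against PBS, where their camera adjusted p was 0.082, 0.14 and 0.066, and the difference between these results was not tested. The lipoprotein list had a median of 0.02, a mean of -0.03 and a downward direction by camera, and the endoplasmic reticulum stress list a median of -0.01 and a mean of 0.02, and neither was called.

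Against both controls 3746 genes changed the same way, 2075 higher and 1671 lower, and 0 changed in opposite ways. Both comparisons use the same mimic libraries. In 50 simulations without any effect the overlap was 0 each time. Hardly any gene can pass the threshold in such data, so this does not measure how much overlap the shared libraries add. Lists of these sizes drawn independently would share 815, a number that leaves the shared libraries out of account. With the mimic libraries split between the comparisons in 6 ways, 1161 to 1807 genes were shared, where independent lists would share 152 to 467.

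Comparing scramble with PBS measures the background of injecting an oligomer of another sequence. With limma 0 of 13636 genes passed an adjusted p of 0.05, the smallest being 0.557, while 434 had an unadjusted p under 0.05. On the recovered reads edgeR called 0 and DESeq2 called 14, and a fit to these libraries alone called 5. The genes with the smallest p, none of them called, had log2 differences of 0.47 for Dhrs7, 1.09 for the estrogen receptor gene Esr1, 0.59 for Atxn1, -0.51 for Zfp36l2, -0.42 for Cpeb1 and -1.16 for Dlec1. Esr1 was 14.7 ± 4.47 in the scramble group (SD, n = 3) and 6.30 ± 1.54 in the PBS group (SD, n = 4). Saa1 differed by -1.11 and Lcn2 by -0.37, neither called. Camera called 4 lists, each with 0 members called over all genes tested and 0 adjusted over the list alone, while the lists of the cell cycle and of endoplasmic reticulum stress, which were not called, each had 1 member higher adjusted over the list alone. Macrophage genes had a median of -0.22, with differences of -0.28 for Slc40a1 and -0.40 for Aif1. Xenobiotic genes had a median of 0.14, with 0.47 for Gstt1 and 0.62 for Gstt3, cholesterol genes a median of 0.12, with 0.37 for Msmo1 and 0.47 for Insig1, and stellate cell genes a median of 0.09, with 0.29 for Col6a1 and 0.21 for Bgn. Their camera adjusted p was 0.00023, 0.00023, 0.0026 and 0.049, and an adjusted p = 0.79 with an estimated correlation for the first 3 and 0.90 for the last. Each of these calls depended on single libraries. Without PBS replicate 2 the macrophage and xenobiotic calls were lost, without scramble replicate 1 the macrophage call, without scramble replicate 2 the cholesterol call, and the stellate cell call without any 1 of 5 libraries and among genes with a mean of at least 5. Each fit with 1 library left out also called 1 to 4 other lists, among them the interferon list upward without PBS replicate 2 and downward without PBS replicate 1, 3 or 4.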

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

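The tests on oligomer injection, on scaling, on the share of hepatocytes, on base composition together with length, and on other splits of the libraries were chosen after the results were seen, as were the patterns of acute phase and interferon genes and of macrophage and stellate cell genes. The site score and the separate tests on base composition and on length were fixed before.

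In 202 groups of 4 libraries, 20 had 1 library far from the other 3 by Dixon's test, where chance gives about 10. In the PBS group, replicate 2 stood apart with Gpnmb at 0.838 against 0.0445 to 0.121 in the others, Cd93 at 1.34 against at least 1.72, Saa1 at 116 against 26.3 to 33.7 and Mia3 at 105 against 137 in the nearest library. PBS replicate 3 stood apart with Oas3 at 0.312 against 0.724 to 0.758, Col4a2 at 6.31 against 5.08 to 5.27, Bgn at 24.2 against 32.0 to 32.3, and 101 Mreads (mega-reads) against 62.8 to 67.2. The Mup rows held 61.9% of the counted reads of that library. Acot1 was 86.5 in PBS replicate 1 against 52.8 to 57.9. In PBS replicate 4 Timd4 was 2.19 against 4.11 to 4.45 and Ppp3ca 23.2 against 22.3 in the nearest library. In the mimic group, replicate 1 had Cyp3a41b at 2.21 against 3.09 to 3.20, Ppp3ca at 12.6 against 15.2 to 15.3 and Reln at 6.78 against at least 14.2. Mimic replicate 2 had Gadd45a at 4.87 against 4.22 to 4.27, Ago2 at 4.13 against 2.35 in the lowest library, and Zfp36l2 at 21.8 against 18.3 to 18.7. Rplp0 was 92.2 in mimic replicate 3 against 106 to 107. Mimic replicate 4 had Cfd at 4.13 against 0.112 to 0.393 and Acot3 at 14.97 against 2.43 to 4.54.

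Of the 86 acute phase and interferon genes, 22 of 35 and 36 of 51 were called higher and 1 and 0 lower in mimic against scramble. An effect of injecting any oligomer is argued against, since their median change in scramble against PBS was -0.065 (quartiles -0.20 and 0.06), compared with 1.08 in mimic against PBS. On the authors' scaling, the lowest median over 3 other scalings was 1.23, with median-of-ratios factors, against 1.24. Library totals shifted the median gene by 0.52, median-of-ratios factors by -0.0092 and quantile normalization by -0.035. None of these shifts could have lowered the median of the 86 genes much, so this test could hardly have come out otherwise and decides little. With 1 mimic sequence, a response to the miR-30c seed and a response to this duplex as such were not separated, and both stay open as hypotheses.

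The mean of genes with miR-30 sites was lower in the mimic group relative to genes without sites. Base composition is argued against as the whole cause, since 1.5% of reordered 7-base sequences gave a difference as low, although their median of -0.11 was most of the observed -0.15. Length is argued against as the whole cause only narrowly: the length-matched difference was 56.9% of the unmatched one, 53.6% to 60.5% with each library left out, where 50% was the bound, so length may account for a large part. The criterion that all leave-one-out values stay above the bound was set after the 56.9% was seen. With length matched, 1% of reordered sequences gave a difference as low, and their median was -0.033. A direct effect of the mimic on part of these genes stays open as a hypothesis.

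Of the macrophage and stellate cell genes, 17 of 29 and 21 of 31 were called higher and 5 and 1 lower in mimic against scramble. A loss of hepatocytes that raises all other cell types alike is argued against, since the median of the sinusoidal endothelium genes was -0.23 (upper quartile 0.08). The smaller median of the macrophage and stellate lists was 1.02. With library totals the endothelium median was positive. A lower share of hepatocytes through more macrophages or stellate cells would not raise endothelial genes, so this test cannot decide it. On the authors' scaling, the lowest median over 3 other scalings, that with quantile normalization, was 0.94 against 1.03. Here too no scaling shifted the median gene far downward, so this test could hardly have come out otherwise and decides little. More of these cells and a change within them both stay open and were not tested.

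Of the 35 splits of the 7 mimic and scramble libraries, 1, the real one, called as many as 4363 genes and the highest other called 1908. Chance is argued against but not excluded, since 1 of 35 is the smallest share these splits can give. The test was chosen after the count was seen. The other splits also mix mimic and control libraries, which widens their spread and lowers their counts. Of the 35 splits of the mimic and PBS libraries, 1, the real one, called as many as 5059 and the highest other called 0. The same limits hold there, so that chance is argued against but not excluded. For scramble against PBS, where limma called 0, edgeR 0 and DESeq2 14, and 434 genes had an unadjusted p under 0.05, all 35 splits called as many, as any split must where the real count is 0, and the highest other called 6, so that the splits decide nothing there.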

How the results depend on the processing

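The scalings by median-of-ratios factors and by library totals, and the fits without mimic replicates 1 and 4, were chosen after seeing the data. The counts in mimic against scramble, in mimic against PBS and against both controls were 2816, 3273 and 2449 among genes with a mean of at least 5, where fewer genes were tested and 2734 of 2739 and 3199 of 3203 retested calls were kept, and camera called 13 and 10 lists. With quantile normalization camera called 14 (9 upward, 5 downward) and 13 (9 and 4). Without mimic replicates 1 and 4 together they were 2548, 2894 and 2103, and with PBS replicate 2 left out too 4276 in mimic against PBS and 3003 against both controls, and the cause was not tested. With library totals Mttp was at -0.23 and -0.33, 2457 of 4363 and 2847 of 5059 calls were kept, and 8 lists were called in scramble against PBS. With library totals, which shift nearly all genes up, the sign turned in mimic against scramble for Becn1 (0.23), Cebpb (0.27), Cnot6l (0.17), Dennd4a (0.078), Nr1d2 (0.15), Sar1b (0.088), Tnrc6b (0.0055) and Uqcrc2 (0.15), and in mimic against PBS for Atxn1 (0.22), Becn1 (0.28), Cnot6l (0.16), Gadd45a (0.063), Nr1d2 (0.13), Sar1b (0.19), Sdha (0.080), Tnrc6b (0.014) and Uqcrc2 (0.22). With an estimated correlation 0, 0 and 0 lists were called in the 3 comparisons. Scramble against PBS had 5 calls in a fit of those libraries alone and 14 with DESeq2, and the cause was not tested. Its site score, 0.0007 in the report's setting, was -0.00286 with 8-base sites, -0.00245 with 2 or more sites, -0.00275 matched on length and -0.00174 at a mean of at least 5.

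With each library left out, the counts ranged from 2824 (without scramble replicate 1) to 4405, from 3758 to 5681, from 0 to 1, and from 2642 to 3825 against both controls. Lists called ranged from 20 to 21, 16 to 19 and 3 to 8, Mttp from -0.89 to -0.74, -1.01 to -0.86 and -0.17 to -0.09, and the score from -0.164 to -0.138, -0.174 to -0.130 and -0.024 to 0.021. The replicate numbers did not pair the libraries throughout: 3 of 10 same-numbered pairs correlated above 0.1 (range -0.28 to 0.26). All 3 were of replicate 3, which had the highest Mup share in each group (61.9%, 58.7% and 47.8%). Scramble 2 correlated best with mimic 4 (0.35). Whether the libraries numbered 3 share a handling step stays open and was not tested. With a replicate block the counts were 3808, 4584, 0 and 3272, lists 20, 16 and 6, and the score -0.152 and -0.149 at exact p of 0.25 and 0.125, the smallest it allows. Over 192 comparisons of 101 named genes, 4183 of 4332 alternatives kept direction and side of the threshold, 123 lost the call, 6 gained it, 17 turned and 3 moved. With 39705157 to 101380174 reads per library, 1 read stood for 0.0114 to 0.0186 scaled CPM, so that values near these rest on few reads, and an effect of depth on the calls was not tested.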

Other observations

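No test in this part was fixed in advance except the sites of other microRNAs, and the remaining values were looked at after the results were seen.

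Among the named genes that were lower in the mimic group than in both controls, full 8-base miR-30 sites stood in the 3′ UTRs of Mttp (1), Mia3 (1), Becn1 (1), Atxn1 (2, at -0.95 against scramble and -0.35 against PBS, where it was 0.22 with library totals and not called without mimic replicates 1 and 4) and Tnrc6b (3). Ago2 had 3 sites of 7 bases, and Map3k5, Elovl6, Cnot6l, Etl4 and Timd4 had 1 each. Zfp36l2, lower against PBS only, had 2. Dhcr7, Rplp0 and Oas3 also had 1 site of 7 bases and were higher. Acot1, Slco1a1, Krt23, Cyp3a11 and Clec4f, which fell by 2.42 or more on the log2 scale against scramble, had 0 sites. The same held for most of the other named genes that were lower against both controls. Mttp, Map3k5 and Becn1 were named as miR-30 targets, so their sites are no separate evidence, and Ppp3ca, also named as one, had 0 sites. Among all genes with a 3′ UTR, 1891 had a site of 7 bases and 9955 had none. The share among the named genes was not tested against this.

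Sites of other microRNAs gave smaller score differences in mimic against scramble. The liver microRNA miR-122 gave -0.0051 (exact permutation p = 0.771), let-7 gave -0.026 (0.143), miR-192 gave -0.049 (0.0286, the smallest the test can give) and the passenger strand of miR-30c gave -0.041 (0.0571), unadjusted values of two-sided tests. Matched on length these were 0.074, 0.044, 0.034 and 0.034, against -0.085 for miR-30. Reordered 7-base sequences with the bases of the miR-30 site had a length-matched median of -0.033. Part of the contrast with the other microRNAs may therefore rest on base composition.

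Libraries within the mimic group differed unequally. The chi-square per degree of freedom between mimic replicates 1 and 4 was 61.0 and between replicates 2 and 3 it was 112, while the other 4 pairs were at 773 to 1333. The highest values were 446 within the PBS group and 364 within the scramble group. Replicates 1 and 4 also had the lower Mup shares, 14.5% and 13.5%, and the higher Saa shares, 2.61% and 2.05%. Both are shares of the same totals, so they are not separate traits.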
